A study of Arabidopsis thaliana with 6 samples.

How the data were processed

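RNA was measured by sequencing of strand-specific libraries made from ribosomal RNA-depleted total RNA of whole seedlings, 3 libraries of wild-type and 3 of fip37-4 LEC1:FIP37, per the labels. The deposited values are FPKM (fragments scaled by transcript length and by the fragments mapped in the library) per transcript, which the authors made with TopHat2 2.0.9 and Cufflinks 2.1.1 on the genome build TAIR10, per the submitters' processing notes. The unit is not written in the files; it was taken from those tools and checked against the values. Whether the counting used the strand is not given in the sources used here, so reads of a gene and of an overlapping antisense gene may not be told apart, and overlapping or near-identical genes are uncertain. Each file lists 36104 transcripts. Values of isoforms were summed per locus, which gave 28141 features, of which 27374 were annotated loci (88 of the chloroplast and 122 of the mitochondrial genome) and 767 assembled transcripts, 458 with TCONS names and 309 with another prefix. The files do not place the assembled transcripts, and they hold no coordinates. Gene symbols, products and transcript lengths came from a RefSeq table of assembly TAIR10.1, matched by locus code for 26701 loci. Because that assembly is named differently from the authors' build, no coordinates are printed, and classes planned for long non-coding RNAs, pseudogenes and transposable elements were replaced by those the files and that table support; the digit or letter after AT in a locus code names the chromosome or organelle genome.

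FPKM are not counts, so no count model was run. The number of fragments per library is unknown, but the smallest values showed steps of single fragments: for transcripts of at least 1000 nt, 100% of the ratios to wild-type replicate 1 lay within 5% of a common factor, which was 1.08 and 0.951 for the other wild-type libraries and 0.924, 1.12 and 0.792 for the fip37-4 LEC1:FIP37 libraries. These factors give relative depth only. For low named genes, the fragments behind a value were estimated from these steps and the length of the transcript in the reference table. None of the reference transcripts was listed at 0 in any library.

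Values were tested as deposited on the log2(FPKM + 0.5) scale, which understates the change of low genes. Features with at least 0.5 FPKM in at least 3 of the 6 libraries were kept, which left 19383. Groups were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust empirical Bayes, genotype as the only term, and Benjamini-Hochberg adjustment; a gene was called at an adjusted p under 0.05, and counts of 2-fold changes also needed an absolute log2 fold change of at least 1. The 22 gene lists, with 409 genes in all, were fixed before the data were examined, as were the comparisons, the tests and the rule for named genes. The lists cover the m6A writer complex, m6A readers and erasers, shoot stem cell regulators, organ boundary, leaf growth and polarity, embryo and seed maturation, nuclear photosynthesis genes, mitosis, DNA replication, histones, cytokinin, auxin, root hair cells, root endodermis, stele and tip, trichome and stomatal lineage, biotic defence, cold, drought and abscisic acid, heat shock, hypoxia, anthocyanin, flowering, and reference transcripts. Of their genes, 389 carried the same symbol in the reference table, as symbol or synonym, 17 had none there and 3 had another without a matching synonym. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Organelle shares were compared with an exact two-sided permutation test, whose smallest p with 3 against 3 samples is 0.1, and gene classes with Fisher's exact test against nuclear protein-coding genes, two-sided and adjusted over classes, with Python 3.11.15, SciPy 1.17.1 and R.

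The text names FIP37, MTA, MTB, VIR, HAKAI, WUS, STM, CLV3, LEC1, ACT2 and UBQ10 always; of each list up to 4 members past the threshold with the largest absolute log2 fold change, or the 2 with the highest mean level where none passed; and the 10 largest positive and 10 largest negative log2 fold changes among called genes with a mean of at least 5 FPKM in the higher group and no overlap between groups. Genes named outside this rule, which are TCONS_00217531 and psbA in the results and those of the closing section, were chosen after their values were seen.

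The fit was tested on simulated data for the comparison of fip37-4 LEC1:FIP37 with wild-type, on 19383 genes with 50 changed at each size. It recovered 10% of genes at an absolute log2 fold change of 0.25, 58% at 0.5, 86% at 1 and 100% at 2, and 8 of 135 calls were false. Few genes changed in the simulation, whereas 58.6% were called in the real data, where the adjusted threshold is therefore less strict. These shares do not give the sensitivity of the real comparison. The alternatives tried were pseudocounts of 0.1 and 1, no filter and a filter of 1 FPKM, median-of-ratios, TMM and quantile normalization, nuclear genes alone rescaled to an equal total, plain empirical Bayes, a replicate block, and leaving out each library in turn. A test of each transcript on its own and a correction for transcript length (a lowess trend on log2 length with a span of 0.3, removed in each library) were chosen after the data were seen. So were gene families found by a scan with camera of 569 words of product names, each held by at least 15 genes, and a set of iron uptake genes; both are in the closing section.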

Results

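RNA levels were measured in whole seedlings of Arabidopsis thaliana, accession Col-0, grown for 5 days on plates under 16 h of light and 8 h of dark at 23 °C. There were 6 libraries in 2 groups of 3 replicates, wild-type and fip37-4 LEC1:FIP37. FIP37 is a subunit of the complex that writes N6-methyladenosine (m6A) into mRNA. The fip37-4 allele disrupts it, and homozygous embryos of strong FIP37 alleles do not survive. The transgene expresses FIP37 from the promoter of LEC1, a gene of embryo development, so that plants can be followed after germination. The comparison asks how the transcriptome of such seedlings differs from that of wild-type. Total RNA had been depleted of ribosomal RNA, and the values are FPKM. The summed FPKM per library lay between 1160321 and 1350343, and from 22472 to 22884 loci had a value above 0. The number of fragments sequenced is not given in the sources used here, but low values moved in steps of single fragments, and on a transcript of 1500 nt a single fragment was worth between 0.0188 and 0.0265 FPKM. The labels do not say whether replicates came from separate plates or sowings, so p-values measure only the spread between these samples, which may be technical.

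FIP37 (AT3G54170), the targeted gene, was higher in the libraries labelled fip37-4 LEC1:FIP37 than in wild-type. Its level was 8.99, 9.03 and 8.96 FPKM in the wild-type libraries and 80.6, 65.0 and 67.5 FPKM in the others. The log2 fold change was 2.91 ± 0.077 (SE; limma adjusted p = 1.97e-07, n = 3 per group). The files do not separate transcripts of the transgene from those of the endogenous gene, so this level is the sum of both, and it does not by itself show a loss of FIP37. Every direction given here is therefore that of the libraries labelled fip37-4 LEC1:FIP37 against those labelled wild-type. LEC1 (AT1G21970) was listed at 0 in 5 libraries and at 0.0325 FPKM in fip37-4 LEC1:FIP37 replicate 2.

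**Figure D1:**
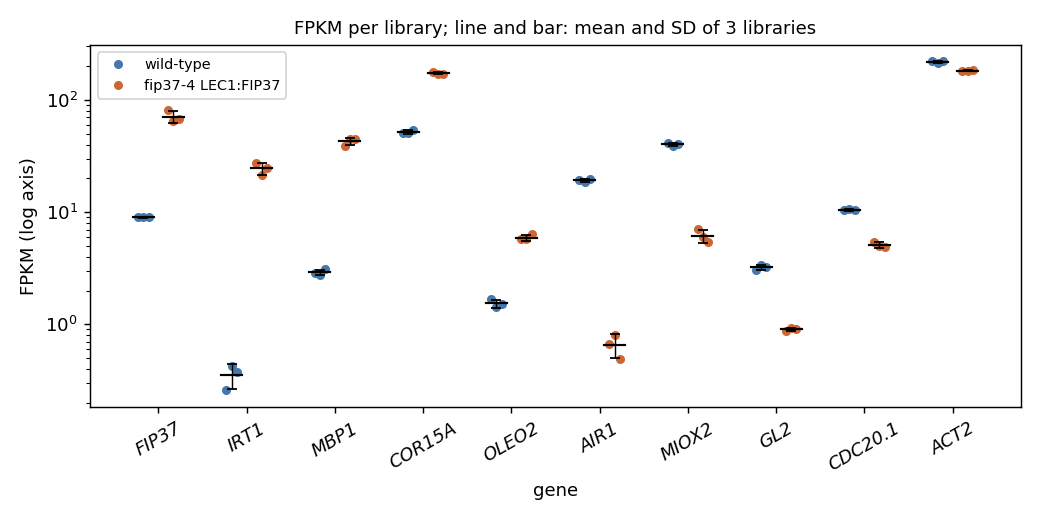
FPKM (log axis) of 10 genes in each of the 3 wild-type and 3 fip37-4 LEC1:FIP37 libraries, as points, with the mean as a line and the SD as a bar. FIP37 is at about 9.0 FPKM in wild-type and from 65.0 to 80.6 FPKM in the other group, and ACT2 is lower in the second group, at 183 against 218 FPKM.

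Of the 5 tested members of the m6A writer complex, 3 rose and 2 did not pass the test. Besides FIP37 these were VIR (AT3G05680), the virilizer-like subunit, from 6.45 ± 0.0965 to 8.90 ± 0.299 FPKM (SD, n = 3 per group here and below), and MTB (AT4G09980), a methyltransferase subunit, from 4.1 ± 0.202 to 5.62 ± 0.349 FPKM. Their log2 fold changes were 0.44 and 0.41. The catalytic subunit MTA (AT4G10760) was at 6.68 ± 0.0263 and 6.63 ± 0.537 FPKM, and the ubiquitin ligase HAKAI (AT5G01160) at 7.84 ± 0.345 and 7.43 ± 0.668 FPKM, with log2 fold changes of -0.01 and -0.07 and limma adjusted p of 0.88 and 0.405. Adjusted over the list alone, 3 members were higher and 0 lower. The list tests count FIP37, which the transgene expresses, so their upward direction is set in part by the construct. No list test without FIP37 is given. Against all other genes the writer list did not pass the camera test (adjusted p = 0.0678, and adjusted p = 0.287 with an estimated correlation), though it did without fip37-4 LEC1:FIP37 replicate 3 (adjusted p = 0.0402), and after removal of a trend with transcript length VIR, then the median of the list, was at 0.12 and lost its call (limma adjusted p = 0.0642). Among 15 tested m6A readers and erasers, 6 rose and 1 fell, with the same counts adjusted over the list alone. The YTH-domain genes ECT8 (AT1G79270), ECT7 (AT1G48110) and ECT6 (AT3G17330) rose by 0.92, 0.56 and 0.52 on the log2 scale, whereas ECT1 (AT3G03950) fell by 0.55. The median of the list was 0.15 (camera adjusted p = 0.0434, but adjusted p = 0.543 with an estimated correlation), and the call was lost without wild-type replicate 3 (adjusted p = 0.0516) or fip37-4 LEC1:FIP37 replicate 1 (adjusted p = 0.0829, median 0.07), with plain empirical Bayes (0.0517) and with each transcript on its own (0.0835, median 0.04).

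Across the transcriptome, 5358 of 19383 tested genes were higher and 5999 lower in the fip37-4 LEC1:FIP37 libraries (limma with Benjamini-Hochberg adjustment, adjusted p under 0.05). Most of these differences were small, since 92.9% of the called genes changed less than 2-fold and 403 genes were at least 2-fold higher and 407 at least 2-fold lower. The first principal component took 76.6% of the variance and separated the genotypes. On the second, with 8.22%, fip37-4 LEC1:FIP37 replicate 1 stood apart at -21.0, against 8.81 and 13.9 for the others of its group and -4.50 to 1.83 for wild-type, and without it 5317 genes were higher and 6047 lower. Pearson correlations of log2 values were 0.993 to 0.994 within wild-type, 0.989 to 0.993 within fip37-4 LEC1:FIP37 and 0.959 to 0.966 between the groups. The groups did not overlap for 12783 genes, or 66.0%, where chance gives 10%. The counts of 2-fold changes depend on the pseudocount, since 652 genes were at least 2-fold higher with 0.1 FPKM added in place of 0.5 and 245 with 1. After the length correction 236 genes were at least 2-fold lower.

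The 10 leading higher genes included 4 of iron acquisition. IRT1 (AT4G19690), the root transporter of ferrous iron, rose from 0.354 ± 0.0874 to 24.5 ± 3.12 FPKM, a log2 fold change of 4.87 ± 0.11 (SE; limma adjusted p = 1.12e-07). FRO2 (AT1G01580), the ferric chelate reductase, rose from 0.223 ± 0.0582 to 5.92 ± 0.125 FPKM. CYP82C4 (AT4G31940), an oxidase of coumarin synthesis induced when iron is short, rose from 0.0566 ± 0.0289 to 9.75 ± 0.193 FPKM, the wild-type values being worth only 1.89, 5.66 and 2.82 fragments. IMA3 (AT2G30766), which encodes a peptide of the iron response, rose from 0.687 ± 0.386 to 12.6 ± 2.40 FPKM. Their log2 fold changes were 3.15, 4.2 and 3.5. The other leading genes were MBP1 (AT1G52040), a myrosinase-binding protein, at 2.91 ± 0.157 and 42.7 ± 3.23 FPKM, and AT2G11270, annotated as a citrate synthase-like protein, at 14.1 ± 4.00 and 193 ± 22.8 FPKM. The assembled transcripts TCONS_00004157, TCONS_00148663 and Novel_000180 completed the 10 with FIP37, with log2 fold changes of 2.69, 2.58 and 2.58.

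Of the 10 leading lower genes, AIR1 (AT4G12550), a lipid-transfer-like gene first found in auxin-treated root cultures, fell from 19.2 ± 0.682 to 0.655 ± 0.157 FPKM, a log2 fold change of -4.1 ± 0.10 (SE; limma adjusted p = 1.49e-07). Its neighbour in the same family, AT4G12545, fell from 11.1 ± 0.278 to 1.16 ± 0.406 FPKM. QQS (AT3G30720), an orphan gene linked to starch content, fell from 15.3 ± 1.64 to 0.528 ± 0.425 FPKM. The E6-like gene AT2G33850 had a log2 fold change of -3.94, the GDSL lipase gene AT5G33370 of -3.46 (-5.22 with a pseudocount of 0.1, since its lower group held 1.00 to 4.00 fragments a library) and AT3G05727, of a pollen coat protein family, of -3.36. HEI10 (AT1G53490), a RING protein of meiotic crossover formation, AGP30 (AT2G33790), a root arabinogalactan protein, and AT4G22513, a lipid-transfer family gene, had log2 fold changes of -2.92, -2.88 and -2.72. MIOX2 (AT2G19800), a myo-inositol oxygenase, fell from 40.1 ± 1.21 to 6.15 ± 0.804 FPKM. Where near-identical copies lie side by side, as for AIR1 and AT4G12545, the authors' counting could split shared reads between them, and the value of each is uncertain.

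Genes of shoot stem cells rose modestly, with 10 of 19 tested members higher and 0 lower, and the same counts adjusted over the list alone. KNAT1 (AT4G08150), a KNOX homeobox gene, rose from 4.63 ± 0.316 to 9.11 ± 0.847 FPKM. The GRAS gene HAM3 (AT4G00150), the receptor kinase gene CLV1 (AT1G75820) and STM (AT1G62360), which maintains the meristem, had log2 fold changes of 0.73, 0.42 and 0.48. STM was low in both groups, at 1.36 ± 0.240 and 2.08 ± 0.332 FPKM, and lost its call without wild-type replicate 2 (limma adjusted p = 0.0515) and after quantile normalization (adjusted p = 0.0538). WUS (AT2G17950), which specifies stem cells, and CLV3 (AT2G27250), their secreted signal, were below the filter and not tested. WUS was listed at 0 in the wild-type libraries and at 0, 0.0908 and 0.0959 FPKM in the others, and CLV3 at 0 in wild-type and at 0.0725, 0 and 0.116 FPKM. The median of the list was 0.18 (camera adjusted p = 0.00494, but adjusted p = 0.149 with an estimated correlation).

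Of 6 tested organ boundary genes, 3 were higher, namely JLO (AT4G00220), LSH3 (AT2G31160) and BOP2 (AT2G41370), with log2 fold changes of 0.51, 0.42 and 0.41. The list did not pass the camera test (adjusted p = 0.448). JLO was near the filter, at 0.336 ± 0.192 and 0.669 ± 0.0778 FPKM, its log2 fold change was 0.91 with a pseudocount of 0.1 and 0.33 with 1, and its call was lost without wild-type replicate 2 or 3 or fip37-4 LEC1:FIP37 replicate 1 or 2 (limma adjusted p from 0.057 to 0.0925), after quantile normalization (0.0969) and with each transcript on its own (0.0739). Genes of leaf growth and polarity went both ways, 7 of 20 higher and 5 lower, with a median of 0.0056 (camera adjusted p = 0.723). TCP10 (AT2G31070), AIL6 (AT5G10510) and AS1 (AT2G37630) rose by 0.74, 0.68 and 0.58 on the log2 scale, and YAB2 (AT1G08465), a YABBY gene of lateral organs, fell by 0.69. Adjusted over the list alone, the counts of both lists were 3 and 0, and 7 and 5.

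Seed maturation transcripts were higher, with 7 of 9 tested embryo and seed genes up and 0 down, over all genes tested and adjusted over the list alone. The other 18 of the list were below the filter, and with no filter the median of the list was 0.22, still with a call (adjusted p = 0.000999). EM6 (AT2G40170), a late embryogenesis protein, rose from 0.798 ± 0.257 to 3.96 ± 0.114 FPKM. The oleosin genes OLEO2 (AT5G40420) and OLEO1 (AT4G25140) rose from 1.54 ± 0.127 to 5.93 ± 0.351 and from 0.583 ± 0.181 to 2.86 ± 0.129 FPKM. The cruciferin gene CRA1 (AT5G44120) rose from 1.52 ± 0.0565 to 5.15 ± 0.476 FPKM. The median log2 fold change of the 9 tested genes was 1.43 (camera adjusted p = 0.000383, but adjusted p = 0.149 with an estimated correlation).

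Nuclear genes of photosynthesis rose as a group, 33 of 43 higher and 3 lower, with the same counts adjusted over the list alone. The light-harvesting genes LHCB2.3 (AT3G27690) and LHCB2.2 (AT2G05070) rose from 471 ± 15 to 1019 ± 16 and from 1241 ± 39.7 to 2410 ± 155 FPKM. RBCS3B (AT5G38410), a small subunit gene of Rubisco, rose from 3758 ± 79.1 to 7212 ± 935 FPKM. LHCB4.3 (AT2G40100) fell instead, from 4.86 ± 0.321 to 1.73 ± 0.383 FPKM. The LHCB2 and RBCS genes are near-identical copies, so the split of reads among them is uncertain. The median was 0.44 (camera adjusted p = 8.99e-07, but adjusted p = 0.482 with an estimated correlation), and it was 0.0070 with no call after quantile normalization (adjusted p = 0.978), where LHCB2.2 and RBCS3B were at 0.42 and 0.44 on the log2 scale.

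Genes of the chloroplast and mitochondrial genomes were also higher. Of 64 chloroplast genes tested, 57 rose and 0 fell, and of 68 mitochondrial genes 51 rose and 2 fell, with median log2 fold changes of 0.67 and 0.58. After quantile normalization the chloroplast median was 0.37 and the mitochondrial 0.66. Both classes were called higher more often than nuclear protein-coding genes, of which 27.3% were higher and 31.9% lower (Fisher's exact test, odds ratios 21.7 and 8.01, adjusted p = 3.44e-24 and 1.28e-15). Genes of a class are not independent replicates, so the Fisher p-values of this paragraph do not measure the spread between libraries. Organelle genes held 50.9 ± 0.301% of the summed FPKM in wild-type and 58.2 ± 1.71% in fip37-4 LEC1:FIP37 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 samples allow). The chloroplast gene psbA, chosen after its values were seen, did not share in this rise. It held 27.11%, 27.06% and 26.51% of the summed FPKM in wild-type replicates 1 to 3. In fip37-4 LEC1:FIP37 replicates 1 to 3 it held 23.18%, 24.33% and 24.99%, and this difference was not tested. The assembled transcript TCONS_00217531, chosen after its values were seen, held 5.10 ± 0.386% and 1.34 ± 0.471% (exact permutation p = 0.1), with 0.80% in fip37-4 LEC1:FIP37 replicate 1 and 1.61% and 1.62% in replicates 2 and 3. Among assembled transcripts, 21 of 293 with TCONS names and 19 of 249 with the other prefix (as in Novel_000180) were lower, fewer than among nuclear protein-coding genes (Fisher's exact test, odds ratios 0.165 and 0.176, adjusted p = 1.93e-23 and 1.94e-19). Of 52 nuclear loci that the reference table lacks, 21 were higher and 5 lower (adjusted p = 0.0837 for higher and 0.000316 for lower, Fisher's exact test). In the class of other nuclear genes 3 were tested and 1 was higher (Fisher's exact test, adjusted p = 1).

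Genes of mitosis fell, 19 of 23 lower and 0 higher, with the same counts adjusted over the list alone. The aurora kinase genes AUR3 (AT2G45490) and AUR2 (AT2G25880) fell by 1.07 and 0.89 on the log2 scale. CDC20.1 (AT4G33270), an activator of the anaphase-promoting complex, fell from 10.4 ± 0.122 to 5.09 ± 0.30 FPKM. The B-type cyclin gene CYCB2;2 (AT4G35620) fell from 3.64 ± 0.181 to 1.69 ± 0.120 FPKM. The median was -0.58 (camera adjusted p = 9.40e-06, but adjusted p = 0.149 with an estimated correlation). DNA replication genes moved less uniformly, 8 of 19 lower and 2 higher, also adjusted over the list alone. The sliding clamp genes PCNA1 (AT1G07370) and PCNA2 (AT2G29570) fell from 13.7 ± 0.370 to 7.69 ± 0.246 and from 16.9 ± 0.705 to 10.5 ± 1.03 FPKM, and the cyclin genes CYCA3;1 (AT5G43080) and CYCD3;2 (AT5G67260) fell by 0.53 and 0.49 on the log2 scale. This list did not pass the camera test (median -0.05, adjusted p = 0.386). Its median ran from -0.10 to -0.05 with 1 library left out and was -0.20 after the length correction, still without a call (camera adjusted p = 0.109).

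Of 13 replication-dependent histone genes, 6 fell and 0 rose, with the same counts adjusted over the list alone. The histone genes AT5G10400, AT5G65360, AT5G10390 and AT5G59690 had log2 fold changes of -0.82, -0.59, -0.52 and -0.47. Their coding sequences are near-identical to those of other histone genes, so single values are uncertain. The list median was -0.24 (camera adjusted p = 0.0434, but adjusted p = 0.556 with an estimated correlation), and the call was lost without wild-type replicate 3 (adjusted p = 0.0638) or fip37-4 LEC1:FIP37 replicate 1 (adjusted p = 0.0905, median -0.16), with a filter of 1 FPKM (0.051), with plain empirical Bayes (0.0517) and after quantile normalization (0.635, median -0.03). These transcripts are short, with a median of 745 nt, and after removal of a trend with transcript length the median was -0.0079 with adjusted p = 0.73. AT5G65360, AT5G10390 and AT5G59690 were then at -0.35, -0.28 and -0.23, still called, and after quantile normalization AT5G65360 and AT5G59690 were at -0.28 and -0.17.

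In the trichome and stomatal lineage, 11 of 17 tested genes fell and 3 rose, also adjusted over the list alone. The trichome regulators GL1 (AT3G27920), MYB23 (AT5G40330) and GL2 (AT1G79840) fell from 2.09 ± 0.288 to 0.248 ± 0.0827, from 2.08 ± 0.492 to 0.357 ± 0.134 and from 3.23 ± 0.178 to 0.900 ± 0.0203 FPKM. EPF2 (AT1G34245), a secreted peptide that limits stomatal lineage entry, fell from 4.28 ± 0.672 to 1.52 ± 0.428 FPKM. The list median was -0.64 (camera adjusted p = 0.00494, but adjusted p = 0.149 with an estimated correlation), and -0.99 with a pseudocount of 0.1. Root hair genes rose, 7 of 8 higher and 0 lower, also adjusted over the list alone. MRH1 (AT4G18640), the expansin genes EXPA7 (AT1G12560) and EXPA18 (AT1G62980), and RHS19 (AT5G67400) had log2 fold changes of 1.02, 0.81, 0.57 and 0.75. Their median was 0.53 (camera adjusted p = 0.00494, but adjusted p = 0.188 with an estimated correlation).

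Markers of the root endodermis, stele and tip were split, 6 of 16 higher and 6 lower, and 7 and 6 adjusted over the list alone. Besides IRT1 and FRO2, the nitrate transporter gene NRT2.1 (AT1G08090) rose to 0.749 ± 0.0771 FPKM from wild-type values worth 1.01, 1.01 and 1.00 fragments, whose spread therefore reflects depth alone, whereas the tonoplast aquaporin gene TIP2;3 (AT5G47450) fell from 11.1 ± 0.211 to 2.3 ± 0.568 FPKM. The list did not pass the camera test (median 0.11, adjusted p = 0.485), and its median was -0.06 after quantile normalization.

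Of 20 genes of cold, drought and abscisic acid response, 11 rose and 0 fell, and 10 rose adjusted over the list alone. COR15A (AT2G42540), a chloroplast protectant of cold-treated plants, rose from 51.6 ± 1.85 to 174 ± 4.42 FPKM, and P5CS1 (AT2G39800), of proline synthesis, from 35.2 ± 1.84 to 65.2 ± 1.62 FPKM. The phosphatase gene HAB1 (AT1G72770) and RD29B (AT5G52300) had log2 fold changes of 0.72 and 0.67, but the HAB1 transcript with the highest level, tested on its own, was at -0.0068 (limma adjusted p = 0.993). The list median was 0.28 (camera adjusted p = 0.000937, but adjusted p = 0.188 with an estimated correlation). Of 6 tested heat shock genes 4 rose and 0 fell, also adjusted over the list alone, with HSP18.2 (AT5G59720) from 2.33 ± 0.560 to 9.73 ± 1.06 FPKM and HSP17.4 (AT3G46230), HSFA2 (AT2G26150) and HSP70B (AT1G16030) at log2 fold changes of 1.41, 0.87 and 0.32. The median was 0.59 (camera adjusted p = 0.0463, but adjusted p = 0.481 with an estimated correlation). The call of the list was lost without wild-type replicate 2 or fip37-4 LEC1:FIP37 replicate 1 or 3 (adjusted p = 0.0517, 0.0748 and 0.0551), with a pseudocount of 0.1, a filter of 1 FPKM or plain empirical Bayes (0.0503, 0.051 and 0.0517) and after quantile normalization (adjusted p = 0.15), and that of HSP70B without wild-type replicate 2 or 3 or fip37-4 LEC1:FIP37 replicate 2 or 3 (limma adjusted p from 0.0544 to 0.0875), and also after quantile normalization (0.137, log2 fold change 0.19), length correction (0.0571) and with each transcript on its own (0.05).

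Of 7 tested genes of anthocyanin synthesis, 4 rose and 0 fell, also adjusted over the list alone. CHS (AT5G13930), chalcone synthase, rose from 17 ± 0.359 to 36.3 ± 1.06 FPKM. UGT75C1 (AT4G14090), the MYB regulator gene AT1G56650 and F3H (AT3G51240) had log2 fold changes of 0.97, 0.80 and 0.64. The list median was 0.64 (camera adjusted p = 0.0317, but adjusted p = 0.188 with an estimated correlation). With a filter of 1 FPKM the median was 0.35 and the call was lost (adjusted p = 0.051), and with no filter it was 0.30. AT1G56650 was at 1.3 with a pseudocount of 0.1. Biotic defence genes went both ways, 8 of 18 higher and 4 lower, and 9 and 4 adjusted over the list alone. CYP71A12 (AT2G30750), of camalexin synthesis, rose from 0.656 ± 0.134 to 4.22 ± 0.154 FPKM, and the immune regulator CBP60G (AT5G26920) from 1.07 ± 0.0597 to 2.46 ± 0.140 FPKM. The defensin gene PDF1.2A (AT5G44420) fell from 0.753 ± 0.177 to 0.0393 ± 0.0681 FPKM. Its paralog PDF1.2B (AT2G26020) was at 0.637, 1.44 and 4.52 FPKM in wild-type and listed at 0 in the 3 fip37-4 LEC1:FIP37 libraries, so no fold is given, and its call was lost without any of those 3 libraries (limma adjusted p from 0.0509 to 0.0786). The defence list did not pass the camera test (median 0.18, adjusted p = 0.219). In the hypoxia list, 1 of 11 genes was higher, SUS1 (AT5G20830) by 0.68 on the log2 scale, and 2 were lower, HB1 (AT2G16060) at -0.89 and HRE1 (AT1G72360) at -0.43, also adjusted over the list alone (camera adjusted p = 0.992). HRE1 lost its call without wild-type replicate 3 (limma adjusted p = 0.0564), after length correction (0.0833, log2 fold change -0.27) and with each transcript on its own (0.0974).

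Hormone genes were mixed. Of 21 auxin genes, 8 rose and 6 fell, also adjusted over the list alone, with the efflux carrier genes PIN4 (AT2G01420) and PIN3 (AT1G70940) and the conjugating enzyme gene GH3.5 (AT4G27260) higher by 0.64, 0.52 and 0.60 and IAA17 (AT1G04250), an auxin repressor gene, lower at -0.52 on the log2 scale (camera adjusted p = 0.431). Of 16 cytokinin genes, 4 rose and 3 fell, also adjusted over the list alone. ARR16 (AT2G40670), a response regulator, and IPT3 (AT3G63110), of cytokinin synthesis, had log2 fold changes of -1.01 and -0.93, and CRF6 (AT3G61630) and the cytokinin oxidase gene CKX5 (AT1G75450) of 0.75 and 0.63 (camera adjusted p = 0.723). Of 12 tested genes of flowering and floral organs, 2 rose and 4 fell, also adjusted over the list alone. SEP3 (AT1G24260), a MADS-box gene, fell by 1.01 on the log2 scale, to 14.9 ± 3.21 FPKM. The flowering repressors FLC (AT5G10140) and TFL1 (AT5G03840) had log2 fold changes of -0.83 and -0.54, and MAF4 (AT5G65070) of 0.46 (camera adjusted p = 0.84). TFL1, at -1.03 with a pseudocount of 0.1 and -0.35 with 1, lost its call without wild-type replicate 1 or 2 or fip37-4 LEC1:FIP37 replicate 1 or 2 (limma adjusted p up to 0.0975), after length correction (0.137, log2 fold change -0.31) and with each transcript on its own (0.0648, still at -0.54), and MAF4 without wild-type replicate 2 or 3 or fip37-4 LEC1:FIP37 replicate 1 (adjusted p up to 0.0852), after quantile normalization (0.097) and with each transcript on its own (0.0782). The flowering, hypoxia and cytokinin lists had medians of 0.05, 0.02 and 0.03 but means of -0.12, -0.05 and -0.0098, and camera gave the flowering list the downward and the others the upward direction.

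**Figure D2:**
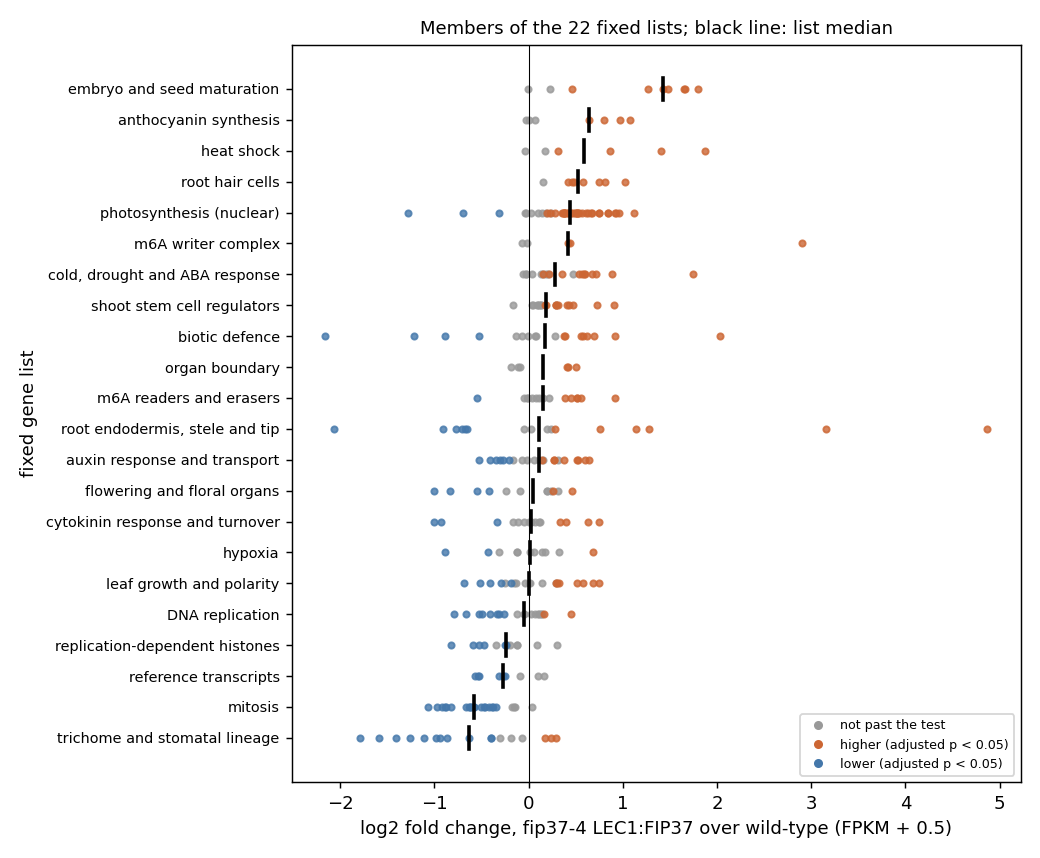
log2 fold changes of the tested members of the 22 lists, fip37-4 LEC1:FIP37 over wild-type, with genes past the limma threshold in colour and the list median as a black line. Medians run from -0.64 for the trichome and stomatal lineage to 1.43 for embryo and seed maturation, and that of root endodermis, stele and tip, at 0.11, turns to -0.06 after quantile normalization.

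Transcripts often used as references were lower. Of 9 such genes 6 fell and 0 rose over all genes tested, and 6 fell and 1 rose adjusted over the list alone. EF1A (AT5G60390), a translation elongation factor, was at 821 ± 23.4 and 555 ± 7.23 FPKM. UBC21 (AT5G25760), TIP41L (AT4G34270) and PP2AA3 (AT1G13320) had log2 fold changes of -0.54, -0.53 and -0.31, that of UBC21 was -0.32 after the length correction, and that of PP2AA3 was -0.19 after quantile normalization. ACT2 (AT3G18780), an actin gene, was at 218 ± 3.66 and 183 ± 2.86 FPKM (log2 fold change -0.26, limma adjusted p = 0.00102), and its call was lost after quantile normalization, at -0.05. UBQ10 (AT4G05320), a polyubiquitin gene, was at 539 ± 15.8 and 578 ± 33.8 FPKM and did not pass the test (limma adjusted p = 0.175), though it did without fip37-4 LEC1:FIP37 replicate 1 (adjusted p = 0.0052). The list median was -0.27 (camera adjusted p = 0.0456, but adjusted p = 0.311 with an estimated correlation), and the call was lost without wild-type replicate 1 or 3 or fip37-4 LEC1:FIP37 replicate 1 or 2 (adjusted p from 0.0509 to 0.0748). It was also lost with nuclear genes only (adjusted p = 0.0523), the filter of 1 FPKM (0.051), plain empirical Bayes (0.0517), quantile normalization (0.28) and each transcript on its own (0.199, median -0.11).

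Changes went with transcript length. Among the shortest of 10 equal groups of transcripts, of 140 to 912 nt, 17.9% of genes were higher and 42.8% lower, and among the longest, of 3126 to 16593 nt, 51.3% were higher and 10.5% lower. Across 18656 genes, which are not independent replicates, the Spearman correlation of log2 fold change with length was 0.257. The stem cell, embryo, photosynthesis, mitosis, root hair, trichome, cold and drought, anthocyanin and reference lists kept their camera calls, at the preset correlation of 0.01, after the trend was removed in each library, an alternative chosen after the data were seen, whereas 3 lists lost theirs. The histone median went from -0.24 to -0.0079, but the medians of the readers and erasers (0.15 before and 0.12 after, adjusted p = 0.117) and of the heat shock genes (0.59 and 0.63, adjusted p = 0.0736) moved little. Log2 fold change also went with mean level, with a Spearman correlation across genes of -0.27, and length and level were weakly related at -0.0761.

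Taking the 22 lists together, 8 passed the camera test as higher and 4 as lower with the preset correlation of 0.01. With an estimated correlation 0 of these 12 camera calls held, and 5 lists had an unadjusted p under 0.05. The limma rotation test fry, which asks whether the genes of a list move on balance in 1 direction and compares no list with other genes, called 18 lists.

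**Figure D3:**
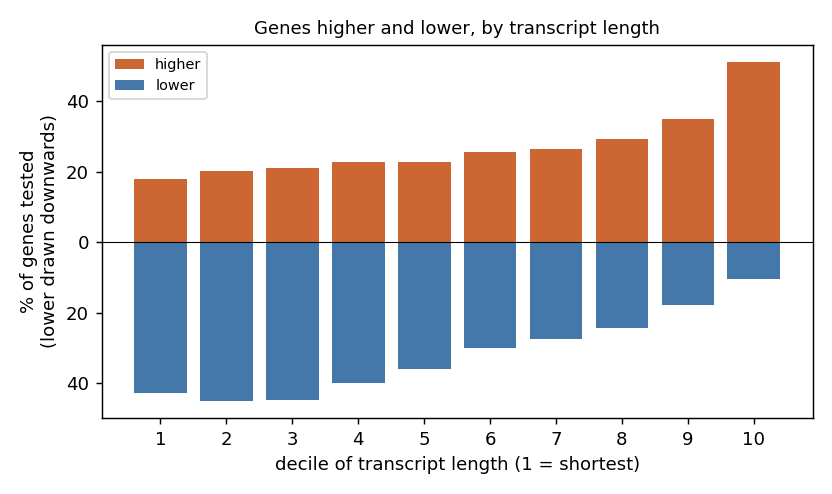
Percentage of tested genes called higher (upwards) or lower (downwards) in fip37-4 LEC1:FIP37, in 10 groups of genes by transcript length from the shortest (1) to the longest (10). The higher share grows from 17.9% to 51.3% and the lower share is 42.8% in the shortest and 10.5% in the longest group.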

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

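The transcript-level test and the length correction were chosen after the data were seen. FIP37 kept its direction and call in every setting run (log2 fold change 2.81 to 2.97 with 1 library left out). The difference in organelle share, which was recomputed with each library left out and has no call, kept its direction (6.29 to 7.90 percentage points). The counts of genes higher and lower stayed within 1.5 times of 5358 and 5999 in all settings, from 4476 to 5317 and from 5274 to 6047 with 1 library left out. The median over all genes, -0.0019 as deposited, moved by less than 0.1 under every scaling. Median-of-ratios, TMM and quantile normalization bring this median near no change by design, so it is no check on the other results. At least 2-fold higher genes numbered 652 with a pseudocount of 0.1 and 245 with 1, since the pseudocount sets the fold of low genes. At least 2-fold lower genes numbered 236 in place of 407 after the length correction.

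Lists called lower numbered 2 in place of 4 with a filter of 1 FPKM, with quantile normalization and with plain empirical Bayes, and 2 to 4 with 1 library left out, 2 without wild-type replicate 3 or fip37-4 LEC1:FIP37 replicate 1. Lists called higher numbered 6 to 8 with 1 library left out. With an estimated correlation 0 lists were called higher and 0 lower (camera). The estimated correlation lay below the preset 0.01 for the stem cell, embryo, trichome and anthocyanin lists (-0.0087, -0.10, -0.046 and -0.014). A higher correlation between genes is therefore not why these lists lost their calls. For the other lists called at the preset value it lay above 0.01, from 0.017 to 0.58. What else ended the calls was not tested. Lists without a call changed the sign of their median. Without the filter it was -0.0024 for cytokinin and -0.049 for root endodermis, stele and tip. With the filter of 1 FPKM it was -0.052 for hypoxia and -0.095 for flowering. After quantile normalization it was -0.011 for leaf growth, -0.034 for cytokinin, -0.055 for root endodermis, stele and tip and -0.0067 for hypoxia. With nuclear genes alone it was -0.017 for leaf growth and -0.0044 for hypoxia, and with each transcript on its own it was -0.029 for flowering. HAB1, a called gene, also turned there, with its highest transcript at -0.0068 and no call. With 1 library left out medians ran from -0.011 to 0.044 for cytokinin, -0.068 to 0.11 for hypoxia, -0.031 to 0.041 for leaf growth and -0.0099 to 0.062 for flowering, and MTA from -0.053 to 0.050. With a filter of 1 FPKM the odds ratio for higher calls was 1.04 for TCONS transcripts and 0 for other nuclear genes, neither with a call.

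Over all settings, 43 comparisons of lists lost a call, 12 of them those with an estimated correlation. Of the 7 differences in the other direction, 6 came from fry, which tests a list against no change and so gives no gained camera call, and 1 was a camera call. For named genes 35 comparisons lost a call with the direction kept and 1 gained one, and HAB1 also lost its call where its direction turned. With a replicate block 5075 genes were higher and 5804 lower, the reference list (adjusted p = 0.0658) and HSP70B (0.0532) lost their calls, and no other list or named gene did. Same-numbered libraries did not deviate together (r of -0.028, -0.049 and -0.057), so the numbers give no sign of pairing. A count model was not run because the files hold no counts. Depth limits what can be said of genes such as WUS, CLV3 and LEC1. Their highest values in any library were worth 4.01, 2.28 and 1.11 fragments.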

Other observations

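The gene families in this part, and the tests of FIP37 labels, LEC1 and root share, were chosen after the data were seen. Genes whose product name holds "ribosomal protein" were lower, 259 of 314 called lower and 18 higher, with a median log2 fold change of -0.65. The respiratory chain set holds genes whose product name includes NADH, ubiquinone or cytochrome c oxidase. Its median was -0.48, with 48 of 66 lower and 4 higher. Of the ribosomal protein genes 0 were organelle-encoded, and whether the respiratory chain set holds such genes was not counted. Genes of the mitochondrial genome went the other way, with 51 of 68 higher, 2 lower and a median of 0.58. Proteasome genes had a median of -0.37, with 34 of 42 lower and 4 higher. Pentatricopeptide repeat genes, most of which act on organelle RNA, had a median of 0.22, with 99 of 229 higher and 12 lower. Immune receptor genes of the TIR-NBS-LRR kind had a median of 0.25, with 35 of 56 higher and 2 lower. These families were picked from a scan of 569 product words on the same libraries, so their tests are not independent evidence. Adjusted over all words, limma's camera with the preset correlation gave p = 2.63e-20 for ribosomal, 2.67e-05 for proteasome, 3.05e-05 for TIR-NBS-LRR, 3.40e-05 for pentatricopeptide and 3.40e-05 for ubiquinone, a word of the respiratory chain set. With an estimated correlation, adjusted over the 7 sets chosen after the data were seen, adjusted p was 0.1 for the ribosomal, proteasome and respiratory chain sets, 0.0688 for TIR-NBS-LRR and 0.0149 for pentatricopeptide, so of these 5 the last kept its call. The other 2 sets in the adjustment were iron uptake and ferritin. No scaling turned a direction, but quantile normalization brought all 5 medians closer to no change. They were then -0.46 for ribosomal protein, -0.38 for respiratory chain, -0.21 for proteasome, 0.11 for pentatricopeptide and 0.21 for TIR-NBS-LRR genes. After the length correction the TIR-NBS-LRR median was 0.07 and its call was lost (camera adjusted p = 0.0731).

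All 12 tested genes of iron uptake rose, with a median log2 fold change of 1.77 (2.75 with a pseudocount of 0.1 and 1.41 with 1), but they were gathered after IRT1 and others were seen to lead the higher genes, so no list test is given. Besides IRT1, FRO2, CYP82C4 and IMA3, the transcription factor genes BHLH38, BHLH39, BHLH100 and BHLH101 had log2 fold changes of 2.18, 1.56, 1.53 and 1.51, and their partner FIT of 0.55. IMA1, IMA2 and F6'H1, of coumarin synthesis, were at 1.39, 1.99 and 1.00. Of the 4 ferritin genes, which store iron, FER4, FER1 and FER3 fell by 0.85, 0.45 and 0.38 on the log2 scale and FER2 rose by 0.47.

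FIP37 was higher in the libraries labelled fip37-4 LEC1:FIP37. A single library under the wrong label is argued against, because the lowest of the 3 held 65.0 FPKM, above every wild-type library. Activity of the LEC1 gene itself in these seedlings is also argued against, since LEC1 reached at most 0.0325 FPKM. An exchange of whole groups, activity of the transgene's promoter at its insertion site, and transcription driven from the inserted DNA of the fip37-4 allele stay open and were not tested.

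Short transcripts were lower and long transcripts higher. Ribosomal protein genes do not carry this alone, since the Spearman correlation with length was 0.24 without them. The trend is also not the whole cause of their lower level, because their median was -0.46 after its removal. A difference in RNA quality or fragment length between libraries may contribute: within fip37-4 LEC1:FIP37, the difference between replicates 1 and 3 went with length at an absolute correlation of 0.21, against 0.257 between the groups, although the group trend was 0.235 without replicate 1. A change in RNA metabolism from the genotype was not tested and stays open.

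The rise of iron uptake genes may reflect the genotype, the iron supply of the plates or the age of the roots, none of which was tested. A larger share of root tissue as the whole cause of the rise is argued against. The 22 other root markers had a median of 0.26 with an SD of 0.806, below the iron uptake median of 1.77 by more than that spread. A part in the rise stays open, because the iron genes were gathered after some led the higher genes, which widens this gap. Root hair genes rose, 7 of 8 higher and 0 lower, while the root endodermis, stele and tip list had 6 higher and 6 lower. A single deviating library is argued against as well, because the median of the iron uptake genes stayed at 1.69 or more with any 1 library left out.

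The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. Genes past the threshold numbered 11357 for the real split and at most 2 for the others, and genes changed at least 2-fold 810 and at most 2. Fixed lists past the camera threshold, at the preset correlation, numbered 12 for the real split and 2 to 5 for every other. That camera test thus called lists in splits with at most 2 called genes, which limits what the 12 calls show. In each of these measures, 1 of the 10 splits, the real one, gave a result as large. Every other split mixes the genotypes, so the genotype difference enters the spread within its groups. Few called genes follow there wherever that difference is large, so the contrast does not measure what chance would give.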
